A study of Mus musculus with 9 samples.

How the data were processed

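Laser-captured choroid plexus of 4 apoE-/- and 5 wild-type samples from male mice, all labelled 78 weeks old, was measured on 1 Affymetrix-type array per sample. Per the labels' protocols, tissue was taken up in Trizol, RNA was purified with a column kit for lipid-rich tissue, and biotin-labelled RNA was made by in vitro transcription. Per the submitters' processing notes the values were made with GCOS 1.4. The deposited table holds a signal intensity on a linear scale and a detection call (present, marginal or absent) for each of 45101 probe sets per array. The background and summary steps behind these deposited intensities are not given in the sources used here. In the files, the mean after trimming 2% of probe sets at each end was 500.0 on every array, so the deposited intensities had been scaled per array. The deposited series matrix held the same intensities in all 405909 values. Detection p columns, 9 in number, were not used, and 18 of their values were above 1.

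Intensities were taken to log2. Array medians on that scale ranged over 0.214, above the limit of 0.1 set for values already scaled between arrays, so they were quantile normalized. Probe sets tested were those other than the 64 controls that were called present on at least 4 of the 9 arrays, 21478 in all. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, genotype as the only term, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets at 0.05. Values given for genes are log2 differences, apoE-/- minus wild-type, or folds from them.

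Genes were named through the platform annotation: 34958 probe sets had 1 symbol, 932 several and 9211 were not listed. By gene ID 34750 of them matched a reference gene table of assembly GRCm38.p6, which was used for names and for which genes neighbour each other. No probe set with several symbols was used for a gene. Probe sets were not averaged. For gene lists and list members, each gene was read by its tested probe set with the highest mean, 11089 genes in all.

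The test, the filter, 29 gene lists with 564 entries, the rule for named genes and the main alternatives were fixed before the data were examined. Of the list entries, 503 were found on the array. The named genes were Apoe, then the 15 largest rises and 15 largest falls among genes with 1 symbol, adjusted p under 0.05 and non-overlapping groups (probe set of smallest p), and up to 4 members of each list with the smallest p. Lists with at least 5 tested genes, 25 of them, were tested with limma's camera (preset correlation 0.01), with the correlation estimated, and with fry, which asks whether a list's genes move one way on balance, or in either direction. No list call of camera's preset correlation held with an estimated correlation: by camera 0 lists passed after adjustment, 3 had an unadjusted p under 0.05, and by fry 3 passed one way (interferon response, MHC class I presentation and complement) and 15 of the 25 in either direction. List means per array were compared with exact permutation tests over the 126 splits of 9 arrays into 4 and 5, two-sided, chosen after the list results were seen. Adjusted over the 25 lists, the smallest exact p was 0.0992.

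The limma step was tested on simulated arrays with the means and spreads of the 21478 probe sets of this comparison. Of 200 changed probe sets it recovered 25.5% at 1.5-fold, 84% at 2-fold and 94.5% at 4-fold, with 1, 4 and 8 unchanged probe sets called. Of 25 simulated lists, a list shifted by 0.5 was called, and so were 3 others, 2 of which shared no genes with it, while with an estimated correlation 0 others were. In 50 simulated sets of 11089 genes with no change, 0 had a list called by camera. The simulated genes were drawn independently of each other, whereas the interferon response list had an estimated correlation of 0.45 in the data. These runs therefore cannot show how often camera's preset correlation calls lists of correlated genes falsely. The alternatives were other scalings, filters, an added offset, other variance priors, array weights, replicate numbers as a block, a brain marker covariate, other thresholds, other list tests and each array left out.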

Results

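Apolipoprotein E (ApoE) is a lipid-carrying protein, and mice that lack it are a model of disturbed cholesterol transport. The choroid plexus is the tissue within the brain ventricles whose epithelium secretes cerebrospinal fluid. Choroid plexus was collected by laser capture microdissection from frozen nervous tissue of male C57BL mice aged 78 weeks on normal chow, and total RNA was hybridised to whole-genome mouse arrays of 45101 probe sets. There were 4 arrays of apoE-/- and 5 of wild-type tissue, each from 1 sample. Between 44.0% and 49.1% of probe sets were called present on an array. Correlations between arrays over the tested probe sets were 0.967 to 0.983 within a group and 0.956 to 0.976 between groups. The question was how old choroid plexus without ApoE differs from wild-type tissue of the same age. Nothing in the labels says how many animals the captures came from, so p-values measure the spread between these samples, which may be partly technical, and the number of arrays limits the precision.

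Apoe itself was read by 1 probe set. Its deposited signal was 12.2, 53.8, 23.5 and 13.5 in apoE-/- replicates 1 to 4, and the probe set was called absent on all 4 arrays. In wild-type replicates 1 to 5 it was 20782, 18252, 23953.1, 18746 and 18488, called present each time. Apoe was at least 956-fold lower in apoE-/- (limma, adjusted p = 5.25e-11), so each array matched its label. Here and below, a bound is given where no array of a group was called present: the brighter group's mean is set against the higher of the dim value and the lowest signal called present on that array, averaged as log2 values. That lowest present signal is not a detection limit, since Apoe was called absent above it on all 4 apoE-/- arrays. Except for Ceacam1 and Akap9, the bounds given here equal the estimated fold. Such a bound does not cover the spread between arrays. Leaving out 1 array or changing a setting can therefore give a smaller fold. For Ceacam1 the log2 difference went from -3.96 to as little as -2.51.

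Of the 15 largest rises in apoE-/- choroid plexus, 8 were members of the interferon response list, beside the lipocalin Apod and the reticulon Rtn2, while the largest falls after Apoe were in Ceacam1, the nuclear RNA Malat1 and Thoc2. Of 21478 probe sets tested, 144 were higher and 412 lower in apoE-/- (limma, Benjamini-Hochberg adjusted p under 0.05). Those with a gene symbol, 125 and 350, came from 113 and 309 genes, with Dusp18 and Sfrp1 in both directions. At least 2-fold differences were found for 19 higher and 150 lower probe sets. The median fold was 1.52 among the higher and 1.82 among the lower probe sets, and the median log2 difference over all tested probe sets was 0.0014. Groups did not overlap for 6.89% of the tested probe sets, against 1.59% by chance. With 1 probe set per gene, the brightest, an alternative chosen after seeing the data, 64 were higher and 67 lower. The counts moved by over 1.5 times when some arrays were left out. The number higher was 88, 64, 56 or 240 without apoE-/- replicate 1, 2, 3 or 4, and 90 or 72 without wild-type replicate 2 or 4, while the number lower was 207 without apoE-/- replicate 3 and 212 without wild-type replicate 4.

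**Figure D1:**
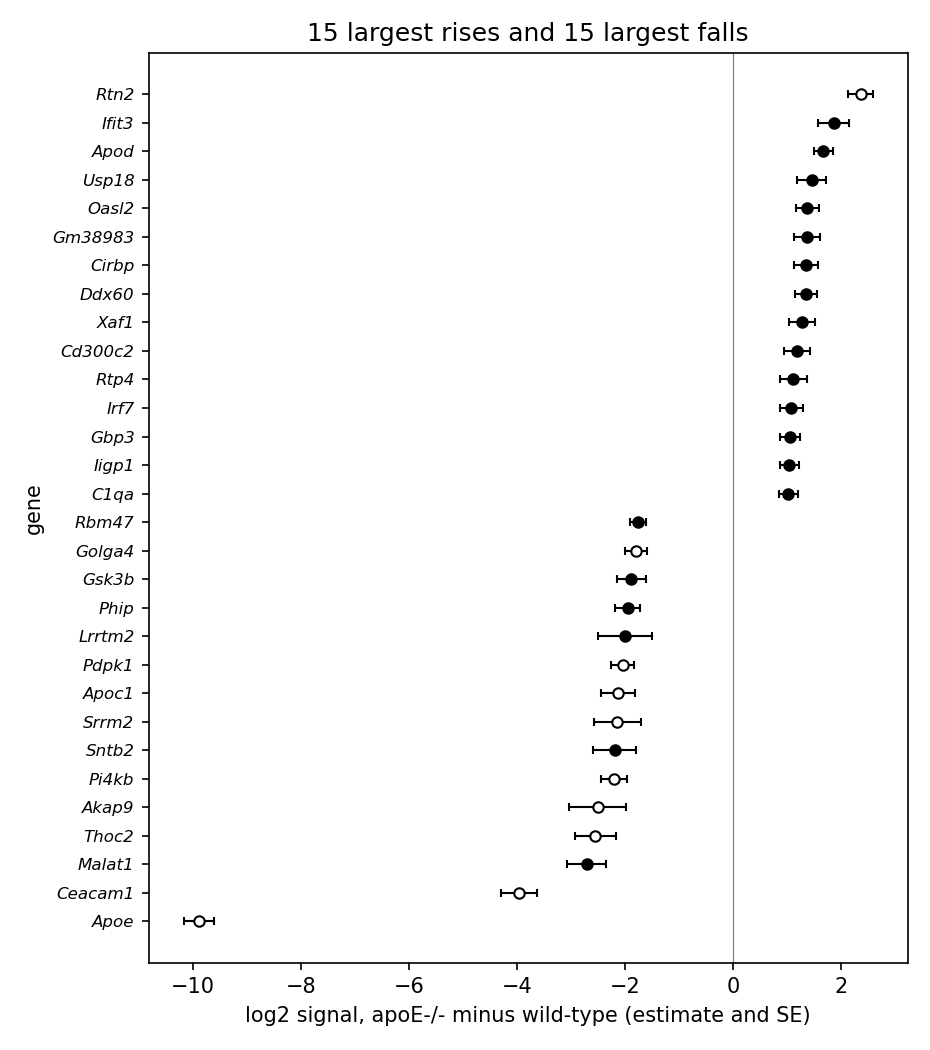
Log2 signal in apoE-/- (n = 4) minus wild-type (n = 5) for the 15 genes with the largest rise and the 15 with the largest fall among those that passed the test with non-overlapping groups. Points are limma estimates and bars standard errors, and open points mark genes with no array called present in 1 group. Apoe lies at -9.90, Ceacam1 at -3.96 and Rtn2 at 2.36, and the other genes lie between -2.71 and 1.87.

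Among the 15 largest rises, Rtn2, a reticulon of the endoplasmic reticulum membrane that lies within 20 Mb of Apoe, as do Gm38983 and Ceacam1, led with a log2 difference of 2.36 ± 0.23 (SE, adjusted p = 1.68e-04). It was called present on 4 apoE-/- and 0 wild-type arrays, at least 5.15-fold higher. Apod, an apolipoprotein of the lipocalin family, rose 3.19-fold (adjusted p = 3.07e-04), and its other tested probe set rose by 1.82 on the log2 scale. Members of the interferon response list were Ifit3 (3.64-fold), Usp18 (2.75-fold), Oasl2 (2.60-fold), Xaf1 (2.42-fold), Rtp4 (2.17-fold), Irf7 (2.12-fold), Gbp3 (2.08-fold) and Iigp1 (2.06-fold). The helicase Ddx60, outside that list, rose 2.56-fold, Cirbp, a cold-inducible RNA-binding protein, 2.56-fold, Gm38983 2.59-fold, Cd300c2 2.27-fold and C1qa, a chain of complement C1q, 2.04-fold. The second probe set of Xaf1 read a log2 difference of 0.23 while that of Iigp1 read 0.66 and passed. Without apoE-/- replicate 3 the adjusted p of Cd300c2 was 0.0637, and that of Rtp4 was 0.0529 to 0.0800 without apoE-/- replicate 1, 2 or 3 or wild-type replicate 2.

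Among the falls, Ceacam1, a cell adhesion molecule, was at least 13.6-fold lower in apoE-/- (adjusted p = 5.11e-05), with 0 of 4 apoE-/- and 4 of 5 wild-type arrays called present. That probe set is not the brightest of Ceacam1, and its others read -1.585 (adjusted p = 5.02e-04) and -0.49 (adjusted p = 0.0840, not passing). Malat1 fell by 2.71 ± 0.36 on the log2 scale (SE, adjusted p = 0.0014). Thoc2, part of the complex that exports messenger RNA, was at least 5.85-fold lower, and Srrm2, a splicing factor, at least 4.42-fold. Bounds were 4.61-fold for the lipid kinase Pi4kb, 4.11-fold for the kinase Pdpk1, 4.42-fold for the anchoring protein Akap9 and 3.47-fold for the golgin Golga4. Sntb2 was 4.58-fold lower, Lrrtm2 4.0-fold, Phip 3.88-fold, the kinase Gsk3b 3.69-fold and the RNA-binding protein Rbm47 3.37-fold. Other probe sets of these genes mostly moved less. Of the 14 falls other than Apoe, 13 had a second tested probe set and 5 had another that also passed. The other probe set of Pdpk1 read -0.09, that of Rbm47 -0.20, that of Pi4kb -0.12 and that of Akap9 -0.03 on the log2 scale, and Srrm2 and Gsk3b each had another reading slightly higher, at 0.08 and 0.11. The call of Lrrtm2 held without apoE-/- replicate 2 or 4 and was lost without any other array, with an adjusted p of 0.117 without wild-type replicate 4, and it was also lost in 7 of 12 other settings (adjusted p up to 0.125). That of Akap9 was 0.0734, 0.0517 and 0.0607 without apoE-/- replicate 3, wild-type replicate 3 and wild-type replicate 4, and that of Srrm2 was 0.0573 and 0.0564 without apoE-/- replicate 3 and wild-type replicate 4.

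Interferon response genes read higher as a list. Each list was read by the brightest tested probe set of each gene, and so were the counts of members below. Of 20 tested members, 12 rose and none fell over all probe sets, and 19 rose adjusted over the list alone, with a median log2 difference of 0.82. Ifit3, Oasl2, Gbp3 and Rsad2 had the smallest p, Rsad2 rising 1.74-fold. The list shift had an adjusted p of 3.9e-20 with limma's camera test and adjusted p = 0.148 with an estimated correlation. Per array, the list mean was 0.51 ± 0.06 (SD, n = 4) in apoE-/- and -0.41 ± 0.38 (SD, n = 5) in wild-type, with no overlap (exact permutation p = 0.00794, two-sided, the smallest that 126 splits allow, and 0.0992 adjusted over the 25 lists). No other list had a lower adjusted exact p. Wild-type replicate 1 was lowest at -1.06, and it also had the highest neuron (0.58) and oligodendrocyte (0.82) marker means. Without it, 11 of the 20 genes rose and the mean log2 difference was 0.76.

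Genes of MHC class I presentation, which display peptides to T cells, also read higher as a list. All 9 tested members read higher, 4 passed over all probe sets and 5 adjusted over the list alone. H2-D1 rose 1.43-fold, B2m 1.37-fold, the immunoproteasome subunit Psmb8 1.56-fold and H2-K1 1.31-fold. The list's adjusted p was 1.30e-06, and adjusted p = 0.148 with an estimated correlation. Per array its mean was 0.20 ± 0.09 (SD, n = 4) against -0.16 ± 0.08 (SD, n = 5), without overlap (exact permutation p = 0.00794). The call of Psmb8 was lost without apoE-/- replicate 1, 2 or 3 or wild-type replicate 2, 3 or 4, and that of H2-K1 without any array but apoE-/- replicate 4 or wild-type replicate 3. Their highest adjusted p, without apoE-/- replicate 3, was 0.102 and 0.181, and H2-K1 also lost the call in 6 of 13 other settings. Other probe sets of H2-K1 read 0.65 (adjusted p = 0.00673) and 0.61 (adjusted p = 0.0339) and passed.

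Markers of macrophages and microglia read higher in the apoE-/- group, with overlap. All 14 tested members were above wild-type, Lyz2 rose 1.76-fold and Ctss 1.54-fold, and 5 passed adjusted over the list alone. Tyrobp (0.57, adjusted p = 0.0577) and Cd68 (0.58, adjusted p = 0.0840) did not pass over all probe sets, though without apoE-/- replicate 4 their adjusted p was 0.0246 and 0.030. The list had a median log2 difference of 0.43 and an adjusted p of 1.30e-06, and adjusted p = 0.315 with an estimated correlation. Its mean per array was 0.22 ± 0.16 (SD, n = 4) against -0.18 ± 0.20 (SD, n = 5), exact permutation p = 0.0238, and apoE-/- replicate 4 at 0.04 lay below wild-type replicate 1 at 0.14. Without apoE-/- replicate 3 the adjusted p was 0.0537 for Lyz2 and 0.0688 for Ctss, and without apoE-/- replicate 2 it was 0.0515 for Ctss. The exact p of the list mean was 0.0536 to 0.0893 without apoE-/- replicate 1, 2 or 3 or wild-type replicate 2, 3, 4 or 5.

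Of 14 complement genes 1 rose over all probe sets, C1qa, and 4 adjusted over the list alone. C1ra (0.60), Serping1 (0.43) and C1qc (0.65) did not pass, but had an adjusted p of 0.0424 without wild-type replicate 3, 0.0252 without apoE-/- replicate 1, and 0.0374 or 0.0188 without apoE-/- replicate 4 or wild-type replicate 1. Of C1qb, the brightest probe set read 0.24 while another read 0.78 and passed (adjusted p = 0.00633). The complement list's adjusted p was 0.0140, and adjusted p = 0.226 with an estimated correlation. Per array the complement mean was 0.14 ± 0.07 (SD, n = 4) in apoE-/- against -0.11 ± 0.08 (SD, n = 5) in wild-type, without overlap (exact permutation p = 0.0159). MHC class II presentation genes all read higher, 7 of 7, with 0 passing singly by limma and 0 adjusted over the list alone, although another probe set of H2-Ab1 read 0.54 and passed (adjusted p = 0.045). Of the 7, 4 had an unadjusted p under 0.05. The median was 0.36, Cd74 read 0.59 and H2-Ab1 0.36, and the list's adjusted p was 0.00969, or adjusted p = 0.322 with an estimated correlation. It was 0.0545 without apoE-/- replicate 3. Of 16 lysosomal and lipid-laden macrophage genes, 1 rose over all probe sets, the protease Ctsl (1.37-fold), and 2 adjusted over the list alone, while Gpnmb read 0.64 without passing. Without apoE-/- replicate 4 the adjusted p of Gpnmb was 0.0319 and that of H2-Ab1 0.0483. The list's adjusted p was 0.0241, and adjusted p = 0.322 with an estimated correlation. It was 0.0597 or 0.0766 without apoE-/- replicate 1 or 3, and 0.0570 without wild-type replicate 2, and it was 0.0612 without quantile normalization, 0.0756 with scaling to the 75th percentile and 0.0802 without the mean-variance trend. Ctsl had an adjusted p of 0.0595 to 0.0881 without apoE-/- replicate 2 or 3 or wild-type replicate 2 or 4. Macrophage markers shared their highest array and their lowest apoE-/- array with these 3 lists, though an association over arrays was not tested. The means of apoE-/- replicate 3 were the highest of the 9 arrays, at 0.42 for macrophages, 0.22 for complement, 0.49 for MHC class II and 0.16 for the lysosomal list. Those of replicate 4 were the lowest of the apoE-/- group, at 0.04, 0.06, -0.14 and -0.04. Wild-type arrays did not keep 1 order: replicate 1 was their highest for macrophages (0.14) but read -0.05 for the lysosomal list. Replicate 3 was their highest for the lysosomal list (0.03) but read -0.24 for macrophages.

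Cholesterol synthesis genes read higher as a list with camera's preset correlation. Of 18 tested, 16 read higher, 2 rose over all probe sets and 7 adjusted over the list alone. The sterol dehydrogenase Nsdhl rose 1.4-fold and squalene epoxidase, Sqle, 1.39-fold, while Msmo1 (0.41) and Insig1 (0.49) did not pass over all probe sets. Other probe sets of Fdft1 (0.49, adjusted p = 0.0181) and Hsd17b7 (0.50, adjusted p = 0.0484) passed where the brightest read 0.35 and 0.29 without passing. The list's adjusted p was 3.87e-06, and adjusted p = 0.322 with an estimated correlation, with an exact permutation p of 0.032 for the array means. Of 15 liver X receptor targets and cholesterol efflux genes, Apod and the desaturase Scd1 (1.36-fold) rose and Apoc1 fell. Adjusted over the list alone, 3 rose and 1 fell, and the list did not pass (adjusted p = 0.0763). It was 0.0297 without apoE-/- replicate 1 and 0.0348 without wild-type replicate 4, 0.011 among probe sets called present on all 9 arrays and 0.00923 with the median over a gene's probe sets. The adjusted p was 0.0539 or 0.0509 for Sqle without apoE-/- replicate 1 or wild-type replicate 4, and 0.0601 to 0.0862 for Scd1 without apoE-/- replicate 2 or 3 or wild-type replicate 2.

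Unfolded protein response genes read lower as a list with camera's preset correlation. Xbp1, the transcription factor of that response, fell by 0.76 ± 0.10 on the log2 scale (SE, adjusted p = 0.00123), the only 1 of 16 to pass over all probe sets, and 2 fell adjusted over the list alone. Creld2 read -1.02 (adjusted p = 0.0671) and Manf -0.62 (adjusted p = 0.153), and 0.00980 and 0.0202 without wild-type replicate 1. The list's adjusted p was 8.15e-04, and adjusted p = 0.322 with an estimated correlation, and the array means gave an exact permutation p of 0.0794.

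Genes that define choroid plexus epithelium did not pass as a shift in 1 direction. Limma's fry test for change in either direction, which 15 of the 25 lists passed, gave an adjusted p of 0.0112. Of 23 tested, 0 passed by limma over all probe sets and 1 adjusted over the list alone, with a median log2 difference of 0.0030 and 3 at an unadjusted p under 0.05. Trpm3 read 0.26 (adjusted p = 0.065, and 0.0435 without wild-type replicate 5) by its brightest probe set, while another probe set of Trpm3 read -1.43 and passed (adjusted p = 0.00610), and Otx2 read -0.24 (adjusted p = 0.140). Of 13 genes of cerebrospinal fluid ion and water transport, 0 passed over all probe sets and 4 were higher adjusted over the list alone, among them carbonic anhydrase Car14 at 0.37 (adjusted p = 0.0525) and the transporter Slc12a4 at 0.46. Their adjusted p was 0.00971 without apoE-/- replicate 4 for Car14 and 0.0447 without wild-type replicate 3 for Slc12a4. That list, with 5 members at an unadjusted p under 0.05, had an adjusted p of 0.0642, and 0.0361, 0.0297 or 0.0334 without apoE-/- replicate 1, apoE-/- replicate 4 or wild-type replicate 5. It was also 0.0488 among probe sets called present on all 9 arrays, 0.0444 with the replicate block and 0.00991 with cyclic loess, chosen after seeing the data. Epithelial junction genes (14 tested, 0 passing, list adjusted p = 0.703) and motile cilia and ependyma genes (15 tested, 0 passing, list adjusted p = 0.348) did not pass, and Foxj1 read 0.63 (adjusted p = 0.227). In either direction the fry adjusted p was 0.00249 for transport, 0.496 for junction and 0.012 for cilia genes. In the junction and cilia lists 0 and 4 members had an unadjusted p under 0.05, and 3550 of all 21478 tested probe sets did.

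**Figure D2:**
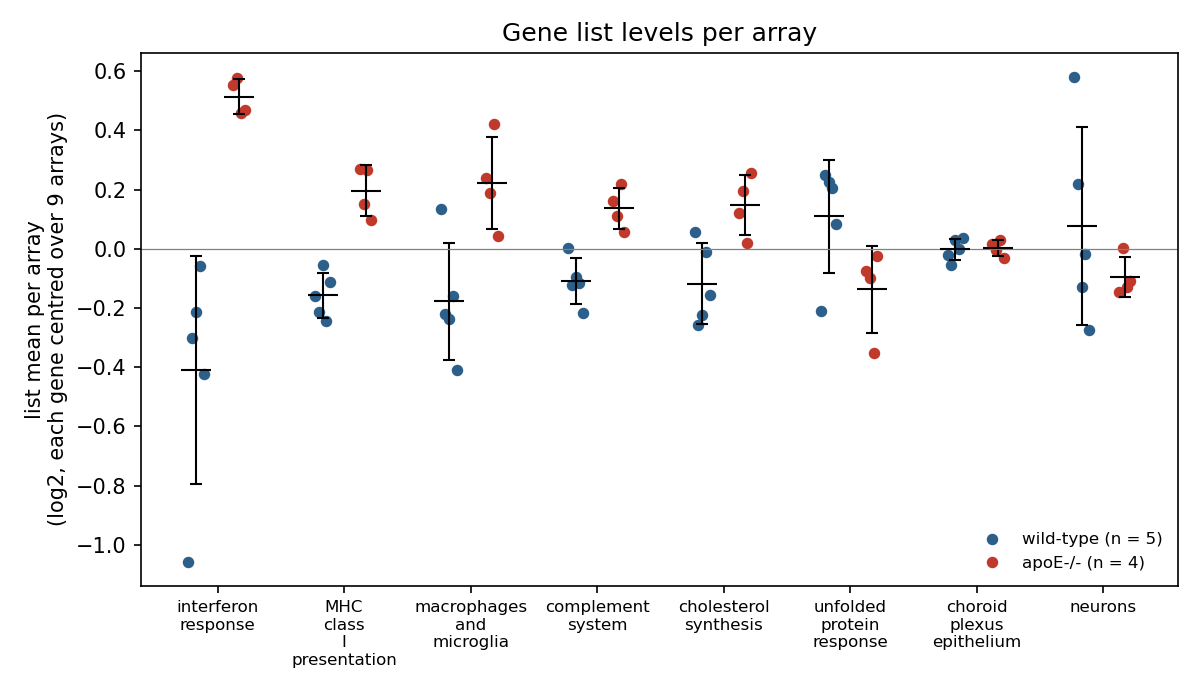
Mean of each gene list per array, as log2 signal with every gene centred over the 9 arrays, for wild-type (n = 5) and apoE-/- (n = 4). Dots are arrays, horizontal marks are group means and bars are SD. The interferon response, MHC class I presentation and complement lists do not overlap between groups, while choroid plexus epithelium lies at 0.00 ± 0.03 in apoE-/- and 0.00 ± 0.04 in wild-type.

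Markers of neural, vascular and stromal cells were measured, the neural ones as a check on the captures. Neurons (10 tested, median log2 difference -0.23, list adjusted p = 0.229), astrocytes (8 tested, 0.19, 0.0763), oligodendrocytes and myelin (6 tested, 0.05, 0.987) and endothelium (13 tested, 0.16, 0.343) had 0 members passing by limma over all probe sets, with 1, 1, 0 and 2 at an unadjusted p under 0.05. Adjusted over the list alone, 1 neuron gene was lower and 0 of the other 3 lists passed. The astrocyte list had an adjusted p of 0.0363 without apoE-/- replicate 3 and 0.0204 without wild-type replicate 1. Snap25 read -1.0 (adjusted p = 0.0940), Mbp -0.76 (adjusted p = 0.448) and Aldh1l1 0.30 (adjusted p = 0.119). These checks leaned on single arrays: Mbp read -0.29 without wild-type replicate 1 and -1.14 without apoE-/- replicate 1, and the neuron list mean went from -0.17 to -0.045 without wild-type replicate 1 and to -0.26 without wild-type replicate 5. The oligodendrocyte mean went from 0.01 to 0.21 and -0.11 without wild-type replicate 1 and 5. Of 16 fibroblast and mural cell genes, Igfbp4 (1.27-fold), the matrix protein Mgp (1.29-fold) and the pericyte marker Rgs5 (1.31-fold) rose, 3 also adjusted over the list alone, and the list did not pass (adjusted p = 0.0763). It was 0.00518 without apoE-/- replicate 1, 0.0498 among probe sets called present on all 9 arrays and 0.044 with the median over a gene's probe sets. Without apoE-/- replicate 3 the adjusted p of Igfbp4, Mgp and Rgs5 was 0.101, 0.102 and 0.153. The calls of Igfbp4 and Mgp were also lost without wild-type replicate 4 and without apoE-/- replicate 1 and 2 respectively, and that of Rgs5 held only without apoE-/- replicate 1. Igfbp4 and Mgp each lost the call in 4 and Rgs5 in 6 of 13 other settings, while 4 other probe sets of Igfbp4 passed, reading 0.40 to 0.71. T cell, B cell, neutrophil and red blood cell lists had 2, 4, 2 and 1 tested genes, too few to test.

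Genes that lie next to Apoe on chromosome 7 moved in both directions. Of 42 tested, 2 rose and 5 fell over all probe sets, and 4 and 8 did adjusted over the list alone. The adjacent apolipoprotein gene Apoc1 was at least 4.37-fold lower, with 0 apoE-/- and 4 wild-type arrays called present. The adhesion molecule Bcam was 2.21-fold lower, the kinase Mark4 1.71-fold lower and Sae1, which activates SUMO, higher by 0.50 on the log2 scale. The list did not pass as a shift in 1 direction (adjusted p = 0.146, or 0.0220 without apoE-/- replicate 2), while fry in either direction gave an adjusted p of 3.13e-10, a test that 15 of the 25 lists passed. The adjusted p of Mark4 was 0.0583 without apoE-/- replicate 3. Its other tested probe set moved slightly the other way, with a ratio of -0.0957 to the log2 difference of the named one.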

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

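The tests of the share of calls around Apoe, of beta-actin and Gapdh, of interferon minus macrophage and minus brain marker means and of the interferon list without wild-type replicate 1, and the count of brightest probe sets, were chosen only after the result was seen.

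Within 20 Mb of Apoe on chromosome 7, leaving out Apoe, 25 of 330 tested probe sets passed (7.58%) against 448 of 17989 elsewhere (2.49%), an odds ratio of 3.209 (95% interval 2.02 to 4.89, Fisher's exact p = 1.71e-06), with 7 higher and 18 lower. Probe sets of 1 gene are not independent, and with each gene counted once 22 of 253 had a passing probe set (8.7%) against 396 of 10785 elsewhere (odds ratio 2.498, 95% interval 1.52 to 3.93), while the highest of 68 stretches of the genome by genes lay on chromosome 16, with 7 of 67 genes (10.45%) and 10 of 133 probe sets (7.52%) passing. Loss of ApoE acting wherever genes lie would give about 8.2, with 14 as the upper end of the 95% range, so the 25 argue against it for this excess, though less firmly given the share on chromosome 16. The values are consistent with a segment of another strain carried along with the targeted gene, which leaves the share on chromosome 16 open, and members chosen after their values were seen are Peg3 (-1.29), Nudt19 (-1.47), Lgals4 (-1.68), Mrps12 (-0.89) and Zfp111 (-1.41), beside Rtn2, Gm38983, Ceacam1, Apoc1, Bcam, Mark4 and Sae1. Whether sequence variants under single probe sets contribute cannot be told apart, since other probe sets of 9 such genes moved by a median ratio of 0.3231 of the passing one, against 0.148 for 308 genes elsewhere (permutation p = 0.0828), too few genes to decide.

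More probe sets were lower (412) than higher (144) in apoE-/-. A trend with gene length over all probe sets of an array is argued against as the whole cause, since removing it left 2.791 times as many lower as higher (321 and 115, from 349 and 125). Length here was the span of the gene on the genome, and genes of lower probe sets were longer (median 51.0 kb against 14.4 kb). An effect of length confined to some probe sets was not tested. RNA degradation cannot be told apart, because the log2 3-prime to 5-prime beta-actin ratio differed by 0.0239 (exact permutation p = 0.865), that of Gapdh by -0.0631 (exact permutation p = 0.635), and 2 control transcripts with this spread decide little. Other probe sets of a lower gene followed by a median ratio of 0.1212, against 0.419 for higher genes (261 and 47 genes, permutation p = 1e-05, the smallest that 100000 resamples give). A change in part of the transcript, read by single probe sets, would give such a difference. The ratio cannot decide this, since the passing probe set was chosen for its smallest p. Lower probe sets were also dimmer than higher ones (mean log2 level 9.04 against 10.11). Among genes with several probe sets 18.1% of lower, 40.3% of higher and 38.9% of other probe sets were the brightest of their gene, a rank that also depends on the probes, and with the brightest alone 64 were higher and 67 lower.

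Interferon response genes were higher in apoE-/-, and wild-type replicate 1 alone is argued against, since without it the mean log2 difference was 0.7622 (adjusted p = 2.79e-22, adjusted p = 0.0485 with an estimated correlation, exact permutation p = 0.0286), whereas over all arrays the list had adjusted p = 0.148 with an estimated correlation. More neighbouring brain tissue in the apoE-/- captures cannot be told apart as a cause. The brain marker mean differed by -0.0057 (exact permutation p = 0.976). That value pools list means that went opposite ways, astrocytes by 0.19 and neurons by -0.17, with oligodendrocytes at 0.01. The interferon minus brain marker mean differed by 0.93 (exact permutation p = 0.0238). That difference was 0.907 to 0.958 without any 1 apoE-/- array, with a p of 0.0714, while the p was 0.0286 without any 1 wild-type array. Of the brain lists astrocytes read highest, at a median of 0.19, without passing (camera adjusted p = 0.0763). The interferon list kept an adjusted p of 2.114e-22 with the brain marker mean as a covariate (adjusted p = 0.17 with an estimated correlation), which met the bound stated beforehand. That mean differed too little for the covariate to remove the call, so this run decides little. More macrophages in the apoE-/- captures cannot be told apart: the macrophage list (14 genes, 13 called present on all 9 arrays, 0 in another list) rose too, with Ctss at 12.05 against 11.42 and Lyz2 at 11.53 against 10.72 on the log2 scale. The interferon minus macrophage mean differed by 0.5231 (exact permutation p = 0.0476), which met the stated bound against macrophages, but a demand that it hold without each array was added after that p was seen, and the p was under 0.05 only without wild-type replicate 4 (0.0286), being 0.0571 to 0.196 without any other array. The difference was 0.283 without wild-type replicate 1 and 0.48 to 0.61 without any other array. An effect of ApoE loss on interferon signalling is a hypothesis that stays open beside more macrophages or more brain tissue in the captures.

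Other divisions of the 9 arrays into 4 and 5 were fitted, 100 in all with the real one. For single probe sets 1 division of the 100, the real one, gave as many higher (144, highest other 14) and 1 as many lower (412, highest other 12). Chance is thus unlikely for these counts but not excluded. All other divisions mix the genotypes in a group, so a real difference widens the spread within their groups and lowers their counts. For gene lists chance cannot be excluded: 5 divisions gave as many higher lists (7, highest other 8) and 77 as many lower (1, highest other 10). The 4 other divisions with as many higher lists kept 3 of the 4 apoE-/- arrays together and the 10 lower lists came from 1 that set all 4 among the 5, so these counts carry part of the real difference.

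Among 234 groups of 4 or 5 arrays, 11 had an array far from the others on the log2 scale, and chance gives about 1 in 20, or 11.7. In wild-type replicate 1, Apod was 10.65 (others 11.42 to 11.58) and Ddx60 6.03 (others 6.69 to 6.96). Il1r1 was 9.95 in wild-type replicate 3, above 9.75 to 9.80. Igfbp4 was 12.95 in apoE-/- replicate 3, above 12.73 to 12.75. In apoE-/- replicate 1, Rgs5 was 12.93, below 13.39 to 13.45, and Mbp was 11.06, above 9.46 to 9.57. The other 5 were clock genes in apoE-/- replicate 4, where Dbp was 10.28 (others 12.70 to 12.75), Nr1d2 12.01 (12.88 to 12.95), Per2 8.19 (9.40 to 9.42), Per3 8.14 (9.58 to 9.71) and Arntl 9.75 (7.25 to 7.53).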

How the results depend on the processing

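The settings without the 20 Mb around Apoe, with cyclic loess, with the gene length trend removed and with 1 probe set per gene were chosen only after seeing the data. Of the 56 genes named in the text that passed, 33 kept the call in every run that included them. The run on probe sets called present on all 9 arrays included only 32 of the 56. The counts of 56 and 33 include Peg3, Nudt19, Lgals4, Mrps12 and Zfp111, which were chosen after their values were seen and all kept the call. None of the named genes or lists that passed changed direction. Lists that had not passed changed sign in 18 of 237 results under other settings and 11 of 153 with 1 array left out, with no call. Calls were lost in 52 of 704 gene results under other settings and in 69 of 504 with 1 array left out, and in 11 of 112 and 4 of 72 list results. Usp18, Xaf1, B2m and Nsdhl lost it only without the mean-variance trend, and Lrrtm2, H2-K1 and Rgs5 in at least 6 settings each. Genes that had not passed did so in 36 of 401 and 22 of 279 results, and such lists in 9 of 237 and 11 of 153.

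Against 144 higher and 412 lower probe sets, no filter on calls gave 81 and 248 (and 2 lower lists), no mean-variance trend 57 and 252, array weights 372 and 706, a 2-fold minimum 19 and 150, an adjusted p under 0.1 325 and 688, and 1 probe set per gene 64 and 67. An estimated correlation gave 0 higher and 0 lower lists. Leaving out 1 array gave 56 to 240 higher and 207 to 529 lower probe sets, 6 to 9 higher lists, and 1 lower list, or 2 without apoE-/- replicate 2 or 4. The cause was not tested. Scalings left 22.4% to 27.4% of calls higher, against 25.9%. The robust prior was not run for lists. Precision for dim probe sets is limited by their signal over background.

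The replicate block gave 180 higher and 421 lower probe sets and 8 and 1 lists. Deviations of same-numbered arrays correlated by 0.1595, -0.015, 0.0307 and 0.0080, and those of differently numbered arrays by -0.1156 to 0.1356. These values show no clear pairing by number, but they were not tested and cannot exclude it.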

Other observations

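The clock gene test was run after Dbp, Nr1d2 and Clock had been seen, on other clock genes.

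Genes of energy metabolism and protein synthesis did not pass in the chosen fit. Of 24 oxidative phosphorylation genes 0 passed by limma over all probe sets and 0 adjusted over the list alone, 4 had an unadjusted p under 0.05, and the list's adjusted p was 0.609, its median (0.0038) and mean (-0.0157) differing in sign. Fatty acid oxidation and PPAR targets (14 tested, 0 passing either way, 4 at an unadjusted p under 0.05) had an adjusted p of 0.166, but passed as lower with no filter on calls (0.023, the mean going from -0.07 to -0.15), and cytosolic ribosomal proteins (15 tested, 0 passing, 1 adjusted over the list alone, 1 at an unadjusted p under 0.05) also 0.166, or 0.0454 without wild-type replicate 3 and 0.0466 with cyclic loess. Of 14 genes of amyloid-beta processing and clearance 0 passed either way, 3 had an unadjusted p under 0.05, the secretase Bace1 read -0.41 (adjusted p = 0.172) and the receptor Lrp1 0.26 (adjusted p = 0.213), with a list adjusted p of 0.703.

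Cytokines and acute inflammation genes went both ways. Of 10 tested, the adhesion molecule Icam1 rose 1.39-fold and the interleukin receptor Il1r1 was 1.67-fold lower, 1 and 1 also adjusted over the list alone, and the list's adjusted p was 0.998, with a median of 0.03 and a mean of -0.01. Over all settings and left-out arrays the list mean ranged from -0.06 to 0.35, and the list's camera adjusted p was never below 0.221. Icam1 lost its call without apoE-/- replicate 1, 2 or 3 or wild-type replicate 2, 4 or 5 (adjusted p up to 0.131), and Il1r1 without apoE-/- replicate 3 (0.0534). Of 13 immediate early and heat shock genes, 11 read lower (median -0.19), and the list, in the lower direction, had an adjusted p of 0.166, but 0.00499 without apoE-/- replicate 4 (mean -0.21). Against that direction Egr1 rose 1.90-fold, 1 also adjusted over the list alone. Egr1 lost its call without apoE-/- replicate 3 or 4 or wild-type replicate 2, 4 or 5 (adjusted p up to 0.112).

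A hypothesis is that tissue was collected at a later circadian phase in most apoE-/- samples. Dbp, whose probe sets read 1.61 (adjusted p = 0.0484) and 1.60 (0.0671), Nr1d2, with 1 probe set at 1.0 (0.0355) but its brightest at 0.70 (0.088), and Clock, with 1 at -0.75 (0.0334) but its brightest at -0.19 (0.544), prompted it. Over 6 evening genes (Tef, Hlf, Per1, Per2, Per3 and Cry2) and 3 morning genes (Arntl, Npas2 and Nfil3), none passing singly by limma, evening minus morning was higher in apoE-/- by 1.7869 (exact permutation p = 0.0317, two-sided), which is consistent with it. Per array it was 1.22, 1.46, 2.21 and -0.92 in apoE-/- replicates 1 to 4 and -1.07 to -0.28 in wild-type, so replicate 4 lay within the wild-type range. The p was 0.0179 without apoE-/- replicate 4, where the adjusted p of Tef, Per2, Per3, Arntl, Npas2 and Nfil3 was 0.000112 to 0.0483, and 0.0714 to 0.114 without any other array. The labels used here give no collection time, so time of day and an effect of genotype on the clock stay open.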
